A study of Mus musculus with 5 samples.

How the data were processed

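RNA sequencing was analysed for 5 libraries of sorted mesenteric lymph node ILC2s of C57BL/6 mice, all taken on day 4 after infection with N. brasiliensis, 2 from mice given the adrenergic agonist clenbuterol and 3 from untreated mice. Per the labels' protocols, cells were sorted, and cDNA was amplified with the SMARTer Ultra Low Input V4 kit. Such libraries carry no molecular identifiers, so floors and other counting limits cover counting error only. The deposited values were raw read counts per gene, 1 table of whole numbers with Entrez gene identifiers, made by the authors before deposit. Per the submitters' processing notes, CASAVA 1.8.2, STAR 2.3.0 and the mouse genome build mm10 were used. The counting program and the strand setting are not given in the sources used here, so reads shared by overlapping, antisense or near-identical genes cannot be assigned, and genes of such families are uncertain. Groups were taken from the sample titles. The labels do not state that the libraries came from separate mice, so p-values measure only the spread between these samples, which may be technical.

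The table held 27179 gene identifiers, of which 25275 (93.0%) matched a symbol in the RefSeq annotation of GRCm38, the assembly that mm10 names. The 1904 without a match took 0.727 to 0.986% of the counts of a library and stayed in the tests under their identifiers. Coordinates are those of the annotated gene, counted from 1. Library totals ran from 13942219 to 22319441 counts, and a floor of 3 counts corresponds to 0.134 to 0.215 CPM. CPM values, the counts relative to the library size, and log2 CPM values were computed with TMM-scaled library sizes, the log2 values with a prior count of 2.

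The main test was edgeR's quasi-likelihood F test (edgeR 4.0.16, R 4.3.3) on the raw counts, with TMM scaling, the filterByExpr default filter, robust estimation and the group as the only term. It left 12685 genes and 3 residual degrees of freedom, and the biological coefficient of variation was 0.371. The threshold was a Benjamini-Hochberg adjusted p of 0.05. The standard error of a log2 fold change was its size divided by the square root of its F statistic. DESeq2 1.42.0, which gave an adjusted p for 14012 genes, and limma-voom with sample quality weights (limma 3.58.1) served as alternatives. Tables were prepared in Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6.

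Gene lists were tested with limma's camera on voom log2 CPM at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the 27 lists with at least 5 tested members. Camera with an estimated correlation, fry, and an exact two-sided permutation of the libraries on the mean level of a list were computed beside it. The 29 lists were fixed before the data were examined, as were the main test, the naming rule and all alternatives except those named as added. They cover type 2 effector molecules, ILC2 identity and receptors, DNA replication and G1/S, mitosis and G2/M, the cyclic AMP and CREB response, adrenergic receptor signalling, NF-kB and AP-1 activation, lymphocyte trafficking, inhibitory receptors and feedback regulators, glycolysis, oxidative phosphorylation, cholesterol and fatty acid synthesis, MYC targets and ribosome biogenesis, the interferon response, endoplasmic reticulum stress and secretion, and apoptosis and survival. Lists for other cell types cover MHC class II presentation, T cells, B cells and plasma cells, myeloid and dendritic cells, NK cells and ILC1s, ILC3s, granulocytes and mast cells, erythrocytes and platelets, and stromal, endothelial and epithelial cells. Lists for RNA and cell handling cover heat shock and dissociation stress, cytoplasmic ribosomal proteins, mitochondrially encoded genes, and nuclear and non-coding RNA. Of 765 entries 760 matched a gene, 4 did not and 1 repeated another of its list. The RefSeq names of the mitochondrial genes were added after the data were seen.

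The genes named in the text were set by a rule. It names Il5, Il13, Il4, Il9, Csf2, Areg, Gata3, Il1rl1, Il7r, Klrg1, Icos, Mki67, Nr4a1, Crem and Pde4b. It adds the 10 genes with the largest positive and the 10 with the largest negative log2 fold change past the threshold, with an average of at least 3 log2 CPM and no overlap between the groups. Predicted gene models, pseudogenes, immunoglobulin and T cell receptor segments, Xist and Y-linked genes are left out of that part, and no gene met it. Of each list it names up to 4 members past the threshold, or the 2 with the smallest p where none passed. Some genes that the rule names are not reported here. Genes outside the rule are stated to be chosen after their values were seen.

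Alternatives were DESeq2-style and upper quartile scaling in edgeR, no filter on low counts, a stricter filter of at least 5 CPM in at least 2 libraries, leaving out each library in turn, the replicate number as a block, thinning every library to the smallest total (seed 1), non-robust dispersion, a fold change of at least 2, and an adjusted p under 0.1. Removing each library's trend with GC content and transcript length by natural splines with 4 degrees of freedom was added after the data were seen, as was leaving the cell cycle genes out of the other lists. GC content and length, from a GENCODE annotation of GRCm38, were known for 12040 tested genes (94.9%).

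The procedures were tested on simulated data, with counts drawn for the 12685 genes from the real means and library sizes and 200 genes changed in each of 10 draws. These 200 were taken from genes with an average of at least 3 log2 CPM, so the rates do not cover lower genes. Many changed genes also loosen the Benjamini-Hochberg cutoff, so the rates do not carry over to data with few changed genes. In the real data edgeR did not call Cebpb, which was 9.47-fold lower with clenbuterol. For this comparison edgeR called 41.0, 93.0 and 98.3% of the genes changed 2-, 4- and 8-fold and 12.4 unchanged genes per draw. DESeq2 called 56.4, 96.1 and 99.1% and 50.3 unchanged genes per draw, and limma-voom 36.6, 89.1 and 98.3% and 11.2. A list whose members were changed 2-fold was called in 10 of 10 draws at the preset correlation and in 4 of 10 with an estimated one, and 6 of 259 tests of other lists were called. Genes were drawn independently of each other, whereas the estimated correlation of the real mitosis list was 0.702. These list rates therefore do not carry over to lists whose members vary together.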

Results

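Group 2 innate lymphoid cells (ILC2s) are lymphocytes without rearranged antigen receptors that release type 2 cytokines in the defence against worms. Clenbuterol is an adrenergic agonist that raises cyclic AMP in the cells it acts on. RNA was sequenced from ILC2s sorted as KLRG1+ CD127+ CD90+ lineage-negative CD45+ cells from the mesenteric lymph nodes of C57BL/6 mice on day 4 after infection with the nematode Nippostrongylus brasiliensis. There were 2 libraries from mice given clenbuterol in the drinking water and 3 from infected mice without the drug. The libraries held 22319441 and 17632812 gene counts in the clenbuterol group and 16416943, 20723623 and 13942219 in the untreated group. Between 14192 and 15084 genes had at least 1 count. The largest share of counts taken by a single gene was 1.58 to 2.15%, and the gene was B2m in every library. A gene without counts in a library could still be present at up to 0.134 to 0.215 CPM, the level of 3 counts.

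The comparison asks what adrenergic stimulation does to gene expression in ILC2s during the infection. In the clenbuterol libraries Cebpb, a basic leucine zipper transcription factor that responds to cyclic AMP and to stress, stood at 15.1 ± 7.19 CPM (SD, n = 2) against 142 ± 17.8 CPM (SD, n = 3) in the untreated libraries, 9.47-fold lower. Crls1, which makes the mitochondrial lipid cardiolipin, was 5.87-fold lower, and Snx20, a sorting nexin that binds the selectin ligand PSGL-1, was 3.64-fold lower. Higher with clenbuterol were Ccr9, a chemokine receptor for homing to the small intestine, at 1.82-fold, and Ptger4, the prostaglandin E2 receptor EP4, at 1.71-fold. Most genes of the type 2 effector, cell cycle and ribosomal protein groups had lower values with clenbuterol, and most of the ILC2 identity group had higher values.

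No single gene passed the main test, edgeR's quasi-likelihood test, which called 0 of 12685 genes. At an unadjusted p under 0.05 that test held 692 genes, 319 higher and 373 lower with clenbuterol, where 634 are expected by chance. DESeq2 called 45 genes, 8 higher and 37 lower, with 971 at an unadjusted p under 0.05. These 971 were counted over all genes with a p-value, which need not be the 14012 with an adjusted p. Limma-voom with sample quality weights called 1, Cebpb, with 881 at an unadjusted p under 0.05. In the simulated draws DESeq2 called 50.3 unchanged genes per draw. Those draws held 200 changed genes, which loosen the cutoff, so this does not tell how many of the 45 are false. No draw without changed genes was run. Of the 10 splits of the libraries into 2 and 3, 4 gave a DESeq2 count as large as the real one, counting the real one, and another gave 187. A call by DESeq2 alone is therefore weak evidence of a change. Its lower calls include the immunoglobulin segments Igkv4-58 and Igkv19-93, which had no counts with clenbuterol and were not in edgeR's test. In 2735 genes, 21.6% of those tested, every library of one group lay above every library of the other, against 20% by chance for 2 libraries against 3. Spearman correlations between libraries of the same group were 0.965 to 0.975, the same range as between the groups. Without clenbuterol 2, edgeR called 1 gene, Cebpb (adjusted p = 0.03).

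Cebpb (Entrez 12608, chromosome 2, 167688915 to 167690432, mm10) had 9.98 and 20.1 CPM with clenbuterol and 157, 122 and 147 CPM without it. Its log2 fold change was -3.24 (SE 0.32) in edgeR, with an adjusted p of 0.0782 there, 1.32e-22 in DESeq2 and 0.0198 in limma-voom. Snx20 (Entrez 71607, chromosome 8, 88626561 to 88636133) stood at 14.3 ± 0.792 CPM (SD, n = 2) with clenbuterol and 52.1 ± 5.11 CPM (SD, n = 3) without, a log2 fold change of -1.87 (SE 0.23). Crls1 (Entrez 66586, chromosome 2, 132846650 to 132866786) stood at 8.12 ± 3.38 CPM (SD, n = 2) and 47.5 ± 9.13 CPM (SD, n = 3), a log2 fold change of -2.55 (SE 0.35). Their adjusted p values were 0.184 and 0.282 in edgeR and 4.94e-12 and 5.08e-10 in DESeq2. Without a filter on low counts edgeR called all 3 of these genes, at adjusted p values of 0.000423 for Cebpb, 0.00668 for Snx20 and 0.00329 for Crls1. Snx20 and Crls1 were chosen after their values were seen.

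**Figure D1:**
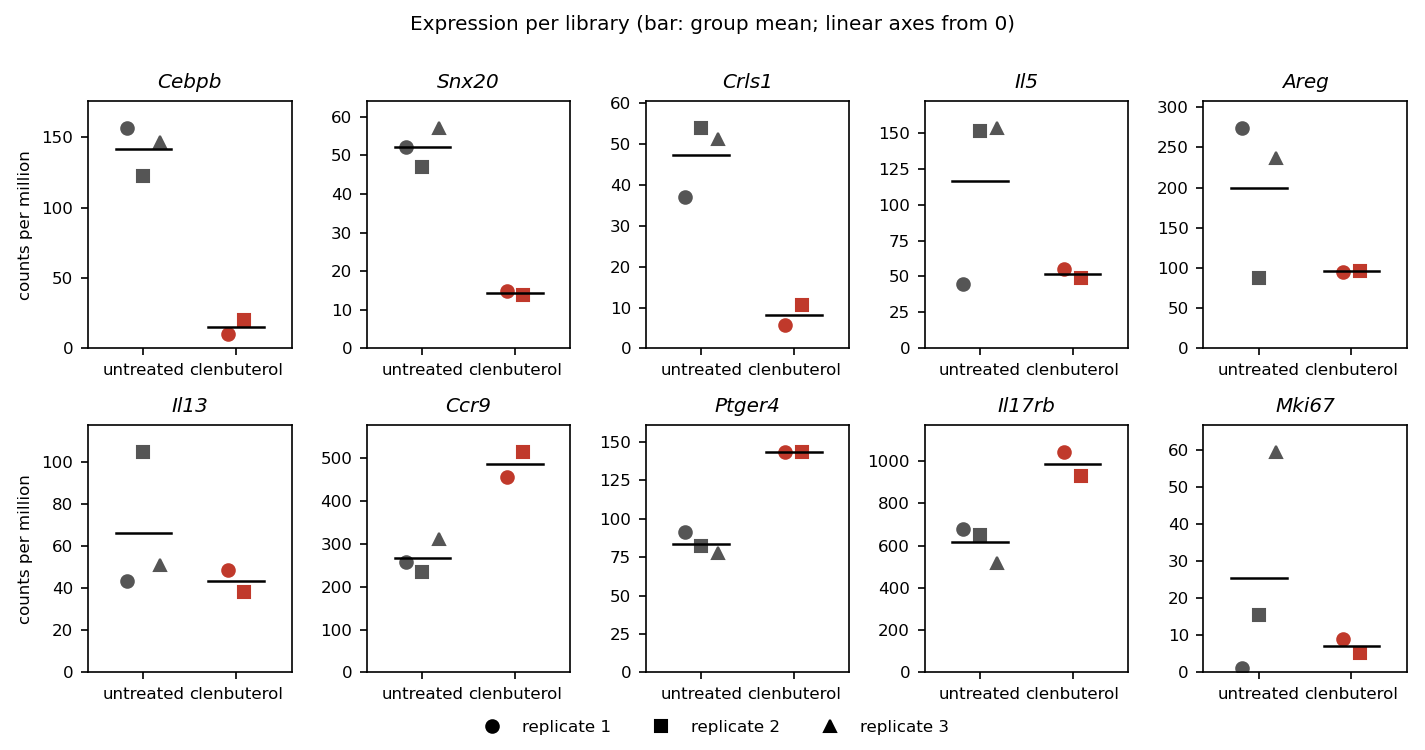
CPM of 10 genes in each library, on linear axes from 0, with a bar at the group mean, grey for untreated and red for clenbuterol, and the replicate number given by the marker's shape. Cebpb lies at 9.98 and 20.1 CPM in the clenbuterol libraries and at 122 to 157 CPM in the untreated ones, whereas Il5 and Areg overlap between the groups.

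Genes for the secreted products of ILC2s had lower values with clenbuterol. Of the 21 tested members of the type 2 effector list, 18 had a lower and 3 a higher value, and the median log2 fold change was -0.41 (limma camera, adjusted p = 0.00329, and adjusted p = 0.926 with an estimated correlation). Il5, the cytokine that drives eosinophils, stood at 52.0 ± 4.65 CPM (SD, n = 2) and 116 ± 62.2 CPM (SD, n = 3), a log2 fold change of -1.16 (SE 0.49). Its untreated libraries stood at 44.6, 151 and 154 CPM, so untreated 1 lay below both clenbuterol libraries. Areg, an epidermal growth factor receptor ligand of tissue repair, stood at 94.8 and 96.9 CPM against 275, 87.5 and 237 CPM, a log2 fold change of -1.06 (SE 0.43). Il13, the cytokine of mucus production and worm expulsion, had a log2 fold change of -0.62 (SE 0.37), and Il4, the cytokine of IgE class switching, had -0.15 (SE 0.20). Csf2, which encodes GM-CSF, was at 258 ± 42.1 CPM (SD, n = 2) and 331 ± 42.4 CPM (SD, n = 3), with each clenbuterol library below each untreated one. Il9 had 8 counts in all, each of them in untreated 3, and was not tested.

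No member of the type 2 effector list passed edgeR, with 0 of 21 over all genes tested and 0 adjusted over the list alone, and 2 lower at an unadjusted p under 0.05. Its mean level was 4.55 and 5.01 log2 CPM with clenbuterol and 5.63, 4.93 and 5.21 without, so untreated 2 lay below clenbuterol 2. The limma camera call on the list was lost without clenbuterol 1 (adjusted p = 0.183, median -0.26) and without untreated 1 (adjusted p = 0.063, median -0.26), and also when each library's trend with GC content and transcript length was removed (adjusted p = 0.059, median -0.22). The log2 fold change of Il13 was -0.12 without untreated 2, and that of Csf2 was -0.21 without clenbuterol 1. The T cell markers had mean levels of 3.61 and 3.82 log2 CPM with clenbuterol and 4.62, 3.33 and 4.67 without, so they were highest in untreated 1 and 3, the libraries with the most Areg. Il5 lies on chromosome 11 at 53720794 to 53725103.

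The receptors and transcription factors that define ILC2s were on balance slightly higher with clenbuterol. Of the 38 tested members of the ILC2 identity list, 25 had a higher and 13 a lower value, with a median log2 fold change of 0.11 (limma camera, adjusted p = 0.0212, and adjusted p = 0.926 with an estimated correlation). The mean level of the list was 7.15 and 7.17 log2 CPM in the clenbuterol libraries and between 6.98 and 7.03 in the 3 untreated ones. Ptger4 (Entrez 19219, chromosome 15, 5233399 to 5244187) stood at 144 ± 0.234 CPM (SD, n = 2) and 83.9 ± 7.06 CPM (SD, n = 3), a log2 fold change of 0.78 (SE 0.15). Il17rb (Entrez 50905, chromosome 14, 29996168 to 30008896), the receptor of interleukin 25, stood at 987 ± 82.7 CPM (SD, n = 2) and 616 ± 85.1 CPM (SD, n = 3), a log2 fold change of 0.68 (SE 0.16). Both rose in DESeq2, with adjusted p values of 0.00516 and 0.0441, and in edgeR their adjusted p values were 0.85 and 0.893. Over all genes tested 0 of the 38 members passed edgeR, and adjusted over the list alone 1 did, Ptger4.

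Among the genes of the sort and of the alarmin response, Klrg1 stood at 1474 and 1534 CPM on average, Il7r, which encodes CD127, at 2416 and 2079 CPM, and Icos, a costimulatory receptor, at 2131 and 1922 CPM with and without clenbuterol. Gata3, the master transcription factor of ILC2s, had a log2 fold change of 0.21 (SE 0.15), and Il1rl1, the receptor of interleukin 33, had -0.09 (SE 0.19). The limma camera call on the ILC2 identity list was lost without clenbuterol 1 (adjusted p = 0.0569), clenbuterol 2 (adjusted p = 0.17, median 0.06) and untreated 2 (adjusted p = 0.106, median 0.07), and with a stricter filter on low counts (adjusted p = 0.0656). Without clenbuterol 2 the log2 fold changes of Il1rl1 and Icos turned to 0.16 and -0.06. Without clenbuterol 1 that of Gata3 was 0.063 and that of Il1rl1 was -0.40, and without clenbuterol 2 that of Il7r was 0.066.

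Chemokine receptors and adhesion molecules showed a small shift to higher values with clenbuterol. Of 27 tested members of the lymphocyte trafficking list 18 had a higher and 9 a lower value, with a median log2 fold change of 0.16 (limma camera, adjusted p = 0.0135, and adjusted p = 0.926 with an estimated correlation). Ccr9 (Entrez 12769, chromosome 9, 123767211 to 123783457) stood at 486 ± 41.4 CPM (SD, n = 2) with clenbuterol and 267 ± 38.7 CPM (SD, n = 3) without, a log2 fold change of 0.86 (SE 0.16). It rose in DESeq2 (adjusted p = 0.00287) and not in edgeR (adjusted p = 0.85). Cd44, a hyaluronan receptor, stood at 117 ± 22.1 CPM (SD, n = 2) and 70.1 ± 19.9 CPM (SD, n = 3). In edgeR 0 of 27 members passed over all genes tested and 1, Ccr9, when adjusted over the list alone. The mean level of the list was 4.91 log2 CPM in untreated 2 and 5.34 to 5.49 in the other libraries. The limma camera call on the list was lost without clenbuterol 1 (adjusted p = 0.0569, median 0.10) and without untreated 2 (adjusted p = 0.347, median 0.09), and the median was 0.079 with each library's trend with GC content and transcript length removed.

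The genes of the stimulated pathway itself showed no common shift. Of the 26 tested members of the adrenergic receptor signalling list 16 had a higher and 10 a lower value, with a median log2 fold change of 0.05 (limma camera, adjusted p = 0.949). Grk6, a kinase that desensitises G protein-coupled receptors, stood at 37.7 ± 4.36 CPM (SD, n = 2) and 79.0 ± 23.0 CPM (SD, n = 3). Of the 31 tested members of the cyclic AMP and CREB response list 15 had a higher and 16 a lower value. The median of that list was -0.00 and its mean -0.41 (limma camera, adjusted p = 0.201). Sik1 and Fosl2, which CREB induces, had log2 fold changes of -1.08 and -1.17, and Pde7a, a phosphodiesterase of cyclic AMP, had -0.41. Fosl2 stood at 15.6 and 12.3 CPM with clenbuterol and 43.4, 13.6 and 37.1 CPM without, so untreated 2 lay below clenbuterol 1. Nr4a1, an immediate early gene, stood at 228 ± 5.89 CPM (SD, n = 2) and 347 ± 139 CPM (SD, n = 3), Crem, a repressor of the pathway, had a log2 fold change of -0.67 (SE 0.38), and Pde4b, a phosphodiesterase, had 0.21 (SE 0.17). Over all genes tested 0 members of either list passed edgeR, and adjusted over the list alone 1 did, Cebpb, of the response list. Without untreated 2 the response list was called lower by limma camera (adjusted p = 6.97e-06, median -0.41). In that setting the heat shock and dissociation stress list was called lower too (limma camera, adjusted p = 8.83e-05). Both lists hold Fos, Fosb, Junb, Atf3, Ier2, Dusp1, Btg2, Klf4 and Cebpb. The call on the response list can therefore not be told apart from a difference in cell handling. Crem stood at 26.2 CPM in untreated 2, below 30.9 and 32.1 CPM in the clenbuterol libraries, and its log2 fold change was -0.30 without untreated 3. Without untreated 1 that of Nr4a1 was -0.23, and without untreated 3 that of Pde4b was 0.13.

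Genes of activation and of its restraint went both ways. The NF-kB and AP-1 list had 12 higher and 16 lower members (limma camera, adjusted p = 0.727), with Tnfaip3, an inhibitor of NF-kB, at 184 ± 6.72 CPM (SD, n = 2) and 354 ± 165 CPM (SD, n = 3) and Nfkbia at a log2 fold change of -0.39. The list of inhibitory receptors and feedback regulators had 15 higher and 13 lower members, a median of 0.01 and a mean of -0.18, and its test pointed down (limma camera, adjusted p = 0.944). In that list Dusp2, a phosphatase of MAP kinases, fell in DESeq2 (log2 fold change -1.56, adjusted p = 0.0236) and Nt5e, which makes adenosine, had a log2 fold change of 0.53. The apoptosis and survival list had 12 higher and 15 lower members (limma camera, adjusted p = 0.727), with the survival gene Mcl1 at -0.67 and the cell cycle inhibitor Cdkn1a at -1.56. Without untreated 1 the log2 fold changes of Tnfaip3, Nfkbia and Cdkn1a were -0.50, -0.21 and -0.92, and without clenbuterol 1 that of Mcl1 was -0.37. In each of these 3 lists 0 members passed edgeR, over all genes tested and adjusted over the list alone.

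Cell cycle genes had lower values with clenbuterol, with a wide spread among the untreated libraries. All 46 tested members of the mitosis list had a lower value, with a median log2 fold change of -1.38 (limma camera, adjusted p = 1.03e-06, and adjusted p = 0.926 with an estimated correlation). Of the 42 members of the DNA replication list 38 had a lower and 4 a higher value, with a median of -0.61 (limma camera, adjusted p = 5.05e-07, and adjusted p = 0.926 with an estimated correlation). The mean level of the mitosis list was 3.19 and 2.26 log2 CPM in the clenbuterol libraries and 2.10, 4.00 and 4.92 in the untreated ones, so untreated 1 was the lowest of all. Mki67, which marks dividing cells, stood at 8.98 and 5.14 CPM against 1.11, 15.4 and 59.5 CPM, a log2 fold change of -1.83 (SE 1.38). Mcm10, needed to start replication, fell in DESeq2 (log2 fold change -3.32, adjusted p = 0.0231), and in edgeR its adjusted p was 0.893. Tk1, an enzyme of thymidine salvage, had a log2 fold change of -2.16, Kif2c, a mitotic kinesin, -2.64 and Ccnb1, which encodes cyclin B1, -2.74.

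In edgeR 0 members of either cell cycle list passed, over all genes tested and adjusted over the list alone. The median of the mitosis list was -0.65 without untreated 3 and -2.08 without clenbuterol 1, and Mki67 was at -0.24 without untreated 3. Ccnb1 was at -1.71 without untreated 3, and without clenbuterol 1 Tk1 was at -3.63 and Kif2c at -4.01. The mean level of the DNA replication list was 4.78 and 3.74 log2 CPM with clenbuterol and 4.09, 5.36 and 5.61 without, so untreated 1 lay below clenbuterol 1. The limma camera call on DNA replication was lost without clenbuterol 2 (adjusted p = 0.0986, median -0.34), and its median was -0.27 without untreated 3 and -0.91 without clenbuterol 1. The B cell markers stood at 3.82 log2 CPM on average in untreated 3 and at 1.37 to 2.41 in the other libraries.

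**Figure D2:**
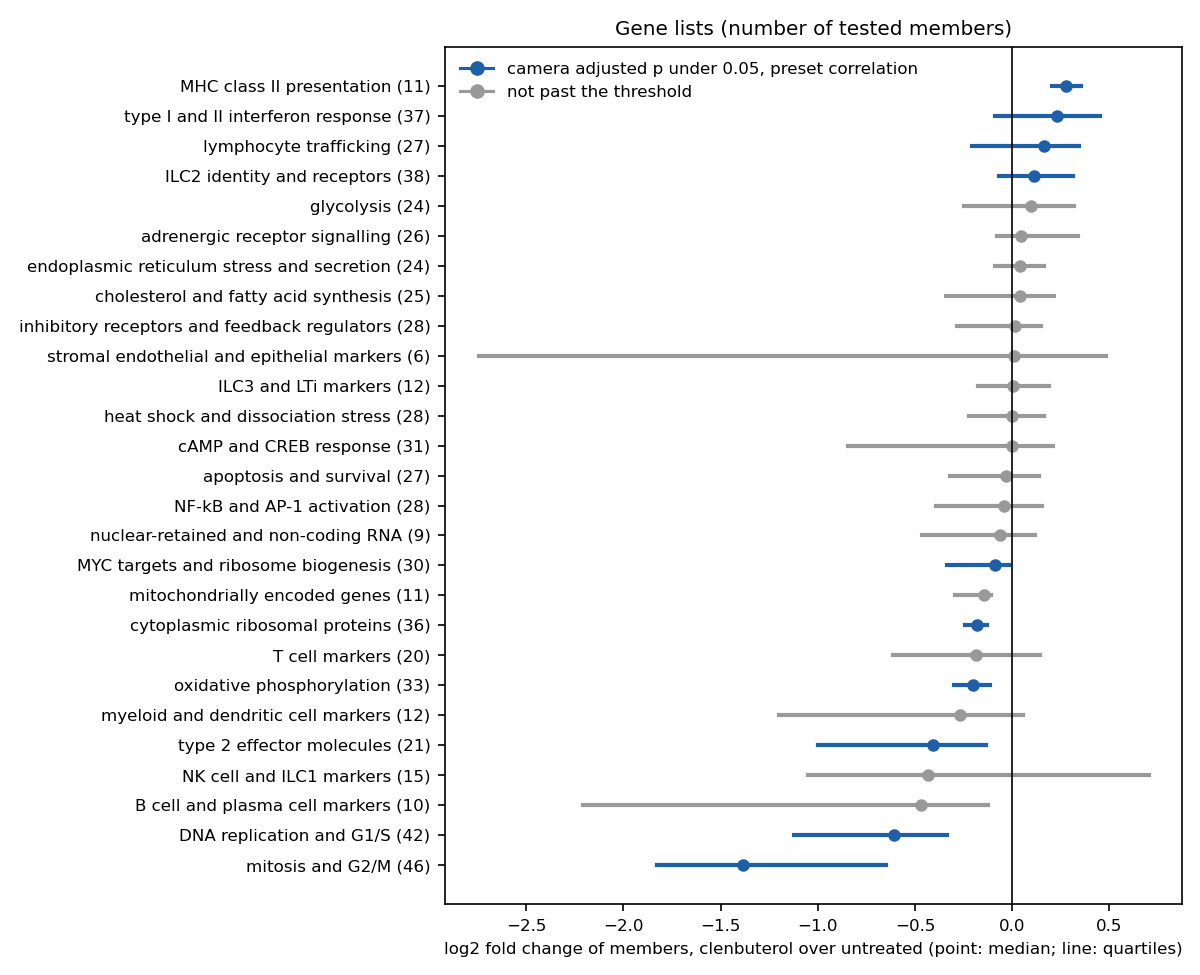
Median log2 fold change (clenbuterol against untreated) of the tested members of each gene list, with lines from the lower to the upper quartile, and blue for lists with a camera adjusted p under 0.05 at the preset correlation. The mitosis list has the lowest called median, -1.38, and the MHC class II list the highest, 0.27.

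Most genes of protein synthesis and respiration had slightly lower values with clenbuterol, but of their 3 lists only the ribosomal one had a mean level that separated the groups. All 36 ribosomal protein genes had a lower value, with a median log2 fold change of -0.18 (limma camera, adjusted p = 7.38e-06, and adjusted p = 0.926 with an estimated correlation), and in 16 of them each clenbuterol library lay below each untreated one (10% by chance in that direction, and 10.8% of all tested genes). Rps2 and Rpl23, of the small and large ribosomal subunits, had log2 fold changes of -0.34 and -0.24. Of the 33 members of the oxidative phosphorylation list 27 had a lower and 6 a higher value, with a median of -0.20 (limma camera, adjusted p = 7.64e-05, and adjusted p = 0.926 with an estimated correlation). Uqcrfs1, a subunit of respiratory complex III, had -0.34, and Sdha, of complex II, went the other way at 0.41. The list of MYC targets and ribosome biogenesis had 23 lower and 7 higher members and a median of -0.09 (limma camera, adjusted p = 0.014, and adjusted p = 0.969 with an estimated correlation). Npm1, a nucleolar chaperone, had a log2 fold change of -0.46 and Odc1, of polyamine synthesis, -0.74.

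In each of these 3 lists 0 members passed edgeR, over all genes tested and adjusted over the list alone. The mean level of the oxidative phosphorylation list was 7.77 and 7.76 log2 CPM with clenbuterol, 7.72 in untreated 1, the lowest of all, and up to 8.04 in the other 2. That of the MYC list was 6.37 and 6.29 with clenbuterol and 6.24, 6.85 and 6.25 without, so only untreated 2 lay above the clenbuterol libraries. The ribosomal protein median was -0.12 without untreated 3, Rps2 was at -0.22 without clenbuterol 2 and Rpl23 at -0.15 without untreated 3. For oxidative phosphorylation the limma camera call was lost without untreated 2 (adjusted p = 0.084). The limma camera call on the MYC list was lost without clenbuterol 2 (adjusted p = 0.0986, median -0.13) and turned up without untreated 2 (adjusted p = 0.197, median 0.09), and it was lost without a filter on low counts (adjusted p = 0.0544). Its median was -0.25 without clenbuterol 1, -0.21 without untreated 1, -0.24 without untreated 3 and -0.16 with each library's trend with GC content and transcript length removed. With that trend removed, the limma camera calls on ribosomal proteins (adjusted p = 0.0813, median -0.08) and oxidative phosphorylation (adjusted p = 0.0728, median -0.08) were lost.

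Interferon-induced genes had mostly higher values with clenbuterol, but their mean level did not follow the groups, at 4.49 and 5.33 log2 CPM with clenbuterol and 4.69, 4.43 and 5.39 without. Of the 37 tested members 24 had a higher and 13 a lower value, and the median log2 fold change was 0.23 while the mean was -0.10 (limma camera, higher, adjusted p = 0.00131, and adjusted p = 0.926 with an estimated correlation). Igtp, an interferon-induced GTPase, stood at 350 ± 68.3 CPM (SD, n = 2) with clenbuterol and 243 ± 8.81 CPM (SD, n = 3) without, and without clenbuterol 2 its log2 fold change was 0.31 against 0.53. In 9 of the members each clenbuterol library lay above each untreated one (10% by chance in that direction, and 10.7% of all tested genes). The genes of antigen presentation by MHC class II had 10 higher and 1 lower member and a median of 0.27 (limma camera, adjusted p = 0.0133, and adjusted p = 0.926 with an estimated correlation). H2-DMa and H2-DMb1, which load peptides, had log2 fold changes of 0.32 and 0.69, and Cd74, the invariant chain, stood at 1054 and 1660 CPM against 1459, 567 and 1191 CPM.

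Over all genes tested and adjusted over the list alone, 0 members of the interferon or MHC class II lists passed edgeR. For the interferon list the limma camera call was lost without clenbuterol 2 (adjusted p = 0.533, median -0.04) and without untreated 2 (adjusted p = 0.106). That on the MHC class II list was lost in limma camera as well, without clenbuterol 2 (adjusted p = 0.309, median 0.06) and without untreated 2 (adjusted p = 0.411, median 0.04), and its median was 0.50 without clenbuterol 1 and 0.42 without untreated 1. Its mean level was 6.07 and 6.20 log2 CPM with clenbuterol and 5.89, 5.56 and 6.22 without, so untreated 3 was the highest of all. The log2 fold change of Cd74 was -0.027 without clenbuterol 2.

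The other metabolic and secretory lists did not pass. Glycolysis had 14 higher and 10 lower members and a median of 0.10 (limma camera, adjusted p = 0.382), with the phosphofructokinase gene Pfkp at a log2 fold change of 0.68 and the lactate transporter gene Slc16a1 at -1.04. Cholesterol and fatty acid synthesis had 13 higher and 12 lower members, a median of 0.04 and a mean of -0.00 (limma camera, adjusted p = 0.727), with Srebf1, a regulator of lipid synthesis, at 0.77 and Msmo1, of sterol synthesis, at 0.50. Endoplasmic reticulum stress and secretion had 13 higher and 11 lower members, a median of 0.04 and a mean of -0.03 (limma camera, adjusted p = 0.92), with Asns, the asparagine synthetase gene, at -1.54 and Ern1, a sensor of unfolded proteins, at -0.71. The log2 fold change of Srebf1 was 0.18 without clenbuterol 1, that of Msmo1 was 0.23 without clenbuterol 2 and that of Slc16a1 was -0.67 without untreated 2. In edgeR 0 members of these lists passed, over all genes tested and adjusted over the list alone.

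Markers of other cell types varied between libraries. T cell markers had a median of -0.19 (limma camera, adjusted p = 0.189), and Cd3e, of the T cell receptor complex, stood at 0 and 2.92 CPM with clenbuterol and 9.34, 4.50 and 10.1 CPM without. Cd8a had no counts in the clenbuterol libraries and stood at 3.28, 0 and 3.00 CPM in the untreated ones, and Cd247, the zeta chain, had a log2 fold change of -1.07. B cell and plasma cell markers had a median of -0.47 while the test pointed up (limma camera, adjusted p = 0.92). Igkc, the immunoglobulin kappa constant gene, stood at 4.90 and 1.81 CPM against 0.681, 0 and 75.2 CPM, Cd79a, of the B cell receptor, at 17.5 CPM in untreated 3 and at most 1.56 CPM elsewhere, and Ighm at 628 ± 138 CPM (SD, n = 2) and 441 ± 99.9 CPM (SD, n = 3). Myeloid and dendritic cell markers had a median of -0.27 (limma camera, adjusted p = 0.0949), with Tyrobp, a signalling adaptor, at 8.77 and 11.0 CPM against 31.7, 20.8 and 7.60 CPM, a log2 fold change of -1.02 that was -0.53 without untreated 1. NK cell and ILC1 markers had a median of -0.43 while the test pointed up (limma camera, adjusted p = 0.961). Gzmb, which encodes granzyme B, stood at 1.91 and 1.69 CPM against 14.2, 161 and 8.12 CPM, and Nkg7, of cytotoxic granules, at 594 ± 0.871 CPM (SD, n = 2) and 372 ± 66.8 CPM (SD, n = 3).

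ILC3 markers had a median of 0.01 and a mean of -0.16 (limma camera, adjusted p = 0.727), with Il23r at a log2 fold change of -2.25 and Ahr at 0.31. Stromal, endothelial and epithelial markers had a median of 0.01 and a mean of -0.86 while the test pointed up (limma camera, adjusted p = 0.961), with Ccl19 at 10.3 CPM in untreated 1 and at most 0.658 CPM elsewhere and Pecam1 at 0.34. Over all genes tested and adjusted over the list alone, 0 members of the 6 lists of T cell, B cell, myeloid, NK cell, ILC3 and stromal markers passed edgeR. Without untreated 2 the T cell list was called lower by limma camera (adjusted p = 8.20e-05), and the myeloid list was called lower without untreated 3 (adjusted p = 0.0455) and without a filter on low counts (adjusted p = 0.0335). When 1 library was left out, the B cell median lay between -2.53 (without clenbuterol 1) and 0.37 (without untreated 3), the NK cell median between -1.47 (without clenbuterol 2) and -0.0091 (without untreated 2), and the myeloid median between -2.21 (without clenbuterol 1) and -0.12 (without untreated 1). The T cell median lay between -0.36 (without untreated 2) and 0.047 (without clenbuterol 1), the ILC3 median between -0.26 (without clenbuterol 2) and 0.19 (without untreated 1), and the stromal median between -2.05 (without clenbuterol 1) and 0.46 (without untreated 1). Without a filter on low counts the B cell, myeloid and stromal medians were -1.67, -1.28 and -1.84, and with the stricter filter the NK cell median was 0.59. Without untreated 3 the log2 fold changes of Igkc and Cd79a turned to 3.33 and 0.97, and that of Gzmb was -2.62 without untreated 2. That of Cd3e was -1.44 without clenbuterol 1 and that of Ighm was 0.26 without clenbuterol 2. Granulocyte and mast cell markers had only 4 tested members and summed to 48.8 to 75.8 CPM, mostly Kit, at up to 67.3 CPM, and erythrocyte and platelet markers summed to 0.145 to 1.22 CPM, so neither list was tested.

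Genes that report on RNA and cell handling varied between libraries of the same group. The heat shock and dissociation stress list had 14 higher and 14 lower members, a median of -0.00 and a mean of -0.20 (limma camera, adjusted p = 0.889). Its mean level was 7.19 and 8.27 log2 CPM in the clenbuterol libraries and 8.66, 6.97 and 8.13 in the untreated ones, lowest in clenbuterol 1 and untreated 2. In limma camera the list was called higher without clenbuterol 1 (adjusted p = 0.0206) and without untreated 1 (adjusted p = 0.0109), and lower without clenbuterol 2 (adjusted p = 0.0073) and without untreated 2 (adjusted p = 8.83e-05). Mitochondrially encoded genes had 9 lower and 2 higher members and a median of -0.15 (limma camera, adjusted p = 0.153), with ND1 and ND2, of respiratory complex I, at -0.25 and -0.20. In limma camera they were called lower without clenbuterol 2 (adjusted p = 0.0362) and without untreated 2 (adjusted p = 0.00326), each with a median of -0.28. The median was -0.064 without clenbuterol 1, -0.088 without untreated 1 and -0.099 without untreated 3. Without clenbuterol 1 both ND1 and ND2 were at -0.13. Nuclear and non-coding RNAs had a median of -0.06 (limma camera, adjusted p = 0.382), with Kcnq1ot1 at -0.46 and Snhg1, a host of small nucleolar RNAs, at -0.38. Their median was -0.36 without untreated 2 and 0.013 without untreated 1. Over all genes tested 0 members of these lists passed edgeR, and adjusted over the list alone 1 did, Cebpb, of the heat shock list. It is the same gene that passed in the cyclic AMP and CREB response list.

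**Figure D3:**
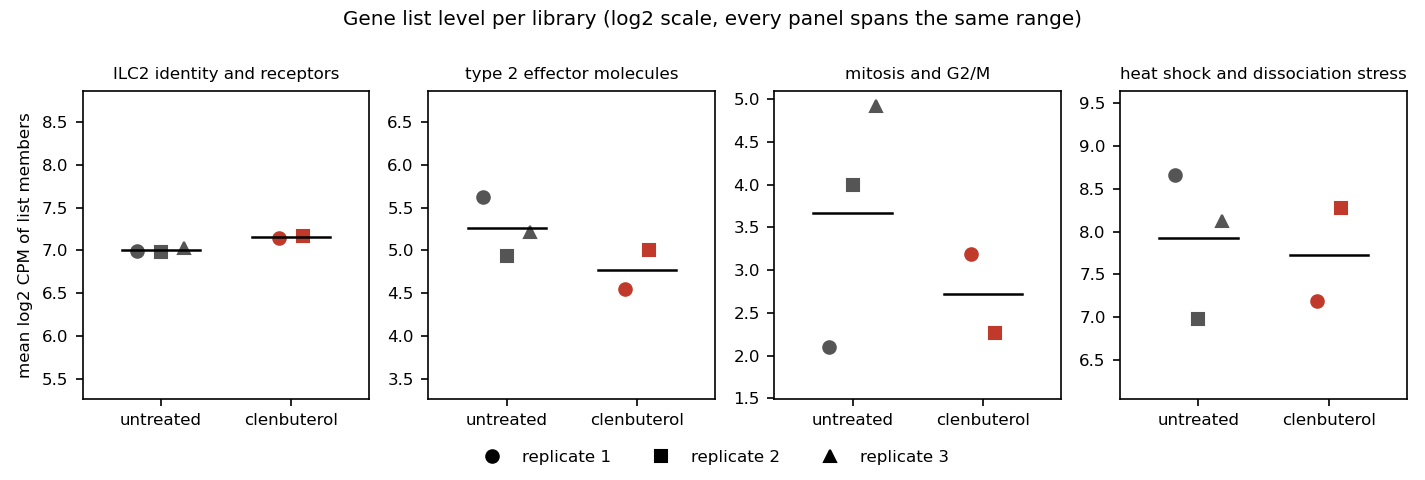
Mean log2 CPM of the tested members of 4 gene lists in each library, with the same span on each vertical axis, grey for untreated and red for clenbuterol. The ILC2 identity list lies at 7.15 and 7.17 with clenbuterol and at 6.98 to 7.03 without, whereas the mitosis list ranges from 2.10 to 4.92 among the untreated libraries.

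Of the 10 lists that passed camera at the preset correlation, 4 were higher and 6 lower with clenbuterol, and with an estimated correlation or in fry 0 of 27 passed. An exact two-sided permutation of the libraries on the mean level of each list gave p = 0.1 for the ILC2 identity and ribosomal protein lists, 0.3 for the type 2 effector list, 0.4 for the DNA replication and oxidative phosphorylation lists, 0.5 for the mitosis and MHC class II lists, 0.6 for trafficking, 0.8 for the interferon list and 1 for the MYC list, and 0.1 is the smallest p that 2 libraries against 3 allow. The markers Cd3e, Igkc and Cd79a, and also Fosl2, Pde7a and Cd74, were chosen after their values were seen.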

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

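The removal of each library's trend with GC content and transcript length and the omission of the cell cycle genes from the other lists were tests chosen only after the results were seen. Against 0 genes in edgeR, the count was 3 without a filter on low counts, 1 with the stricter filter, 45 in DESeq2, 1 in limma-voom, 1 at an adjusted p under 0.1, and 0 to 1 when each library was left out. It was 0 with the other scalings, after thinning, without robust dispersion, with the GC and length trend removed and with a minimum fold change of 2. Against 10 lists, camera with an estimated correlation called 0 and fry called 0, and leaving out each library gave 7 to 11. The count of lists was 10 with the other scalings, without a filter and after thinning, 9 with the stricter filter, 7 with the GC and length trend removed and 8 without the cell cycle genes. Where clenbuterol 1 or 2 was left out, the remaining library was assumed to vary like the untreated ones. Thinning to the smallest total ended no call, and genes near the floor of 0.215 CPM in untreated 3 are limited by depth.

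The adjusted p of Cebpb ran from 1.32e-22 in DESeq2 to 1.00 in edgeR over the alternatives. That of the mitosis list ran from 1.37e-25 to 0.963 in camera and fry, DNA replication from 4.78e-22 to 0.963, interferon from 2.16e-09 to 0.963, oxidative phosphorylation from 2.74e-09 to 0.963, ribosomal proteins from 2.20e-06 to 0.963, type 2 effectors from 1.92e-05 to 0.963, MHC class II from 0.000359 to 0.963, trafficking from 0.00091 to 0.963 and ILC2 identity from 0.00342 to 0.926.

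Some directions turned, most of them in lists and genes that passed in neither setting, and the cause was not tested. The MYC list turned higher without untreated 2 (limma camera, adjusted p = 0.197, and 0.00013 to 0.197 over the libraries left out). The heat shock list turned higher without clenbuterol 1 and untreated 1 (limma camera, adjusted p = 0.0206 and 0.0109, and 8.83e-05 to 0.974 over the libraries left out). Other lists turned in at least 1 library left out, none past the threshold in the turned direction. Over the libraries left out their limma camera adjusted p ran from 6.97e-06 to 0.618 for cyclic AMP, 0.786 to 0.957 for adrenergic signalling, 0.133 to 0.809 for NF-kB, 0.175 to 0.982 for inhibitory receptors, 0.0789 to 0.846 for glycolysis, 0.231 to 0.945 for cholesterol synthesis, 0.242 to 0.913 for endoplasmic reticulum stress and 0.103 to 0.968 for nuclear RNA. It ran from 8.20e-05 to 0.91 for T cells, 0.213 to 0.968 for B cells, 0.435 to 0.647 for NK cells, 0.321 to 0.982 for ILC3s and 0.665 to 0.947 for stromal cells. Without a filter the B cell, stromal and heat shock lists turned (limma camera, adjusted p = 0.873, 0.252 and 0.958), after thinning the B cell list (0.98), with the stricter filter the adrenergic list (0.957), with the GC and length trend removed the adrenergic and stromal lists (0.715 and 0.848) and in fry the inhibitory list (0.963). Over the libraries left out, the log2 fold change ran from -0.40 to 0.16 for Il1rl1, -0.34 to 0.021 for Il4, -0.18 to 0.049 for Klrg1, -0.065 to 0.33 for Icos, -0.027 to 0.63 for Cd74, -3.42 to 0.72 for Hspa1a, -1.23 to 0.70 for Dnajb1, -0.057 to 0.93 for Gzma, -3.79 to 3.33 for Igkc, -4.67 to 0.97 for Cd79a and -2.0 to 1.03 for Lyz2. With the GC and length trend removed Il4 was at 0.12 and Klrg1 at 0.089, and in limma-voom Igkc was at 0.54 and Lyz2 at -0.23. Of the other values of named genes, 1670 kept their direction and side of the threshold and 49 passed it only in the alternative. Since no gene passed the main test, no named gene could lose a call, and keeping its side means passing in neither setting. Of the other values of lists, 319 kept both direction and side, 39 lost the call and 8 gained one. Gzma and Lyz2, granzyme A and lysozyme, were chosen after their values were seen.

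With the replicate number as a replicate block, edgeR called 0 genes, with 221 at an unadjusted p under 0.05, and camera called 10 lists. The log2 fold changes of Mki67, Igkc, Cd79a, Lyz2, Hspa1a and Dnajb1 turned to 0.56, 3.70, 0.63, -0.36, 1.32 and 0.44. No clenbuterol library shares the number of untreated 3, so that library adds nothing to the treatment effect in this fit. The block also leaves fewer residual degrees of freedom than the main fit. The medians moved from -1.38 to -0.41 for mitosis, -0.61 to -0.25 for DNA replication, 0.16 to 0.33 for trafficking, 0.27 to 0.47 for MHC class II, 0.23 to 0.36 for interferon, -0.18 to -0.12 for ribosomal proteins and -0.09 to -0.17 for MYC. The NK cell, stromal and inhibitory lists turned too, without passing (limma camera, adjusted p = 0.26, 0.354 and 0.928). No label pairs the libraries, and across 8654 genes, which are not independent replicates, the deviations of same-numbered libraries correlated at -0.22 and -0.32. Clenbuterol 1 with untreated 2 gave 0.32 and clenbuterol 2 with untreated 1 gave 0.22, the same values mirrored because 2 libraries deviate equally from their mean, and untreated 3 gave -0.12 and 0.12. The numbers were not taken as pairs.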

Other observations

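The tests of GC content and transcript length, of depth, of myeloid and B cell markers and of cycling between libraries were chosen only after the results they bear on were seen.

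Among genes picked out by eye were 2 receptors of neuropeptides, which passed no test. Vipr2, a receptor of vasoactive intestinal peptide, stood at 282 and 251 CPM with clenbuterol and 219, 195 and 73.6 CPM without, a log2 fold change of 0.71 (SE 0.40). Nmur1, the receptor of neuromedin U, stood at 590 and 521 CPM against 317, 581 and 304 CPM, so untreated 2 lay above clenbuterol 2, a log2 fold change of 0.47 (SE 0.27). Without untreated 3 these fold changes were 0.36 and 0.30, and without untreated 2 that of Nmur1 was 0.84. In edgeR both had an adjusted p of 0.9. Among the 45 genes called by DESeq2, Ptpn6, which encodes the phosphatase SHP-1, rose from 136 ± 31.2 CPM (SD, n = 3) to 324 ± 122 CPM (SD, n = 2), with a log2 fold change of 1.25 in edgeR and 0.80 without clenbuterol 2, and Cers4, a ceramide synthase, rose from 69.9 ± 7.79 CPM (SD, n = 3) to 127 ± 4.01 CPM (SD, n = 2). Siah2, a ubiquitin ligase of the hypoxia response, fell from 151 ± 24.9 CPM (SD, n = 3) to 70.9 ± 10.7 CPM (SD, n = 2), and Gnb1, a G protein beta subunit, fell from 263 ± 37.1 CPM (SD, n = 3) to 150 ± 25.5 CPM (SD, n = 2). Their DESeq2 adjusted p values were 0.00681, 0.00509, 0.000945 and 0.0267, and edgeR's were 0.85, 0.85, 0.85 and 0.893. These 6 genes were chosen after their values were seen.

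Stress genes divided the libraries across the groups. Hspa1a, an inducible chaperone of the HSP70 family, stood at 27.3 CPM in clenbuterol 1 and 4.03 CPM in untreated 2, against 482 CPM in clenbuterol 2 and 439 and 435 CPM in untreated 1 and 3. Dnajb1, its co-chaperone, stood at 362 and 171 CPM in the first pair and at 1316, 1511 and 861 CPM in the others. Both were chosen after their values were seen. The 5 libraries make 10 splits into 2 and 3, too few for a share under 0.05. The split of clenbuterol 1 and untreated 2 from the rest gave 187 genes in DESeq2, the highest of the other splits, against 45 for the real one. Nearly as many came from untreated 2 and 3 against the rest (160) and clenbuterol 2 and untreated 1 against the rest (145). These counts do not single out a pair, and whether the samples hold a structure was not tested. The 50.3 unchanged genes per draw that DESeq2 called in the simulation are no measure for them, because those draws also held changed genes. Clenbuterol 1 and untreated 2 are also the deepest libraries, at 22319441 and 20723623 counts. No label gives a batch, and no fit with such a term was run. The sample descriptions number the clenbuterol libraries apart from the untreated ones, without saying what the numbers mean. A difference in collection or preparation that goes with the groups could not be told apart from the drug. The DESeq2 count was as large as the real one in 4 of the 10 splits. The count of lists was 10 in the real split and up to 16 in the others, and as large in 5 of the 10. In edgeR the count was 0 in all 10, with 692 genes at an unadjusted p under 0.05 in the real split and up to 1216 in the others, and the smallest adjusted p was 0.0782 in the real split and down to 0.0716 in another.

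The lower values of Cebpb, Snx20 and Crls1 are the sharpest separation between the groups among single genes by DESeq2's adjusted p. A smooth bias shared by genes of like GC content or transcript length is argued against as the source of changes this large. The trend was weak, with Spearman correlations of the log2 fold change of 0.121 with GC content and 0.120 with length. With that trend removed the median log2 fold change of the 3 genes was -2.47 against -2.55 before. In edgeR the adjusted p of each was then 0.244, where that of Cebpb had been 0.0782. Such a trend cannot show a bias particular to single genes, which was not tested. For myeloid cells in the untreated sorts, which the lineage gate would remove, the median log2 fold change of the markers does not decide, since it was -0.27 (SD 1.14, 12 tested of 23 markers) but -1.28 over 21 markers without a filter and -2.21 over 18 without clenbuterol 1, where Cebpb was at -2.82. The mean level of these markers leaned the same way, at 2.20 and 1.25 log2 CPM with clenbuterol and 2.44, 2.14 and 2.46 without. Clenbuterol 1 lay above untreated 2 there. The abundance of the markers argues against the cells this list marks. Their sum, in which abundant members weigh most, was 296 and 280 CPM with clenbuterol and 377, 285 and 301 CPM without. Lyz2 stood at 21.0, 8.77 and 13.8 CPM in untreated libraries where Cebpb had 157, 122 and 147 CPM. It stays open, as a hypothesis, whether the drug may lower these genes. Chance could too, since edgeR's adjusted p for Cebpb was 0.0782, as could a difference between the mice or in their collection or preparation.

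The cell cycle lists were lower with clenbuterol, but untreated 1 had the lowest level of the mitosis list of all 5 libraries. Cycling that varies between libraries regardless of the drug may account for this, since 5 of the 10 splits gave a difference in the mitosis list as large as the real one, -0.95 on the log2 scale, and the highest other was 1.94. Cycling B cells are argued against as the source in untreated 2, where the B cell markers stood at 1.38 log2 CPM and Cd79a at 0.656 CPM. In untreated 3 these markers stood at 3.82 against at most 2.41 elsewhere, with Cd79a at 17.5 CPM and Mki67 at 59.5 CPM, and because the number of B cells behind them is unknown, cycling B cells and cycling ILC2s cannot be told apart there. The lineage-negative CD90+ CD127+ sort would remove B cells, and of the 18 B cell markers 10 were tested, while Ighm stood at 349.1 to 726 CPM in every library.

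The ribosomal protein and oxidative phosphorylation lists were lower by a small amount in most members, although untreated 1 had the lowest mean level of the oxidative phosphorylation list of all 5 libraries. After thinning to the smallest library at least 0.942 of both medians remained and both calls stayed. Thinning keeps the expected ratio of each gene, so this bears only on counting noise. Other differences between libraries that go with depth were not tested. A bias in GC content or transcript length could account for much of the shift, since at most 0.413 of either median remained with that trend removed, from -0.18 (SD of members 0.10) to -0.08 (SD 0.12) for ribosomal proteins and from -0.20 (SD 0.18) to -0.08 (SD 0.14) for oxidative phosphorylation. Both limma camera calls ended, at adjusted p values of 0.0813 and 0.0728, as did that on the type 2 effector list, at 0.059, whose median went from -0.41 to -0.22, and whether the smaller medians or the shift in the other genes ended them was not tested. These transcripts are short, with median lengths of 992 and 1427.5 bases, and whether a real decrease of short transcripts is removed along with the bias stays open.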
